A study of Mus musculus with 8 samples.

How the data were processed

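Messenger RNA levels were measured in sorted haematopoietic stem cells from fetal liver on 8 arrays, 2 from wild-type, 3 from ADAR1 heterozygous and 3 from ADAR1 null mice. RNA was biotin-labelled with an amplification kit. The deposited values are linear intensity per probe set, and per the labels the authors summarised them with RMA; its software and version are not given in the sources used here. The arrays differed in their quartiles (upper quartile 3.98 to 4.51 on the log2 scale), so they were not left identically distributed. The linear medians were 7.06 to 7.91 and the highest values 17105 to 21192. No per-sample column was left unused (0 of them), and raw image files were not analysed here.

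Log2 was taken of the values as deposited. Of 45101 probe sets, 64 controls were left out of testing and 45037 were tested. The annotation assigned 34945 probe sets to a single gene, 932 to several and 9160 to none; 34741 symbols were matched to the reference by gene number, which served for names only. Coordinates were not used here. Each gene was represented by its brightest probe set, the one with the highest mean log2 value over all 8 arrays among those naming it alone (18193 genes). Background on each array was the highest of 27 control probe sets for Bacillus transcripts, and a group counted as at background where all its arrays were at or below that level.

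Groups and comparisons were fixed before the data were examined, as were the 25 gene lists, the rule for named genes and the alternatives except those said to be added. A 3-group linear model (limma 3.58.1 on R 4.3.3, lmFit and eBayes without trend, 5 residual degrees of freedom) gave null minus wild type, null minus heterozygous and heterozygous minus wild type; a 2-group model with 6 residual degrees of freedom gave null minus all controls. Tests were two-sided, p was adjusted by Benjamini and Hochberg over all tested probe sets, and the threshold was an adjusted p of 0.05. Error terms of fold changes are limma standard errors, and of group means and scores standard deviations over mice. Replicates were numbered in the order of deposit and pair nothing across groups.

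Lists were tested with camera at a preset correlation of 0.01, with p adjusted over 25 lists in 3 comparisons, 75 tests. Of these, 23 passed, 13 as higher and 10 as lower; the type I interferon list against wild type and against heterozygous, 2 calls, held with an estimated correlation, and with fry 9 of the 75 tests passed, which fell on 5 lists. Fry tests whether a list's genes move on balance 1 way and compares no list with other genes. The score of a list on an array is the mean over its genes of the log2 difference from the control mean, tested by exact permutation of 3 null and 5 control arrays (56 splits); comparisons of 3 arrays with 2 or 3 cannot give an exact p below 0.1. Lists were also set beside 10000 random lists matched on expression, which leave out correlation among the genes of a list. Member counts were made over all genes and adjusted over the list alone.

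The lists were type I interferon-induced genes; interferon-inducible GTPases and interferon-gamma-type targets; MHC class I antigen presentation; interferon ligands, receptors and receptor kinases; A-to-I editing enzymes and relatives; transcripts with known A-to-I recoding sites; and neighbours of Adar on chromosome 3. Cell type lists covered stem and progenitor, erythroid, myeloid and granulocyte, macrophage, lymphoid progenitor, megakaryocyte, mast, hepatocyte and hepatoblast, and endothelial and stromal cells. The rest were p53 targets, cell death effectors and regulators, proliferation genes, cytosolic ribosomal proteins, the unfolded protein and integrated stress response, NF-kappaB targets and inflammatory cytokines, cholesterol biosynthesis, sex-linked transcripts and housekeeping genes. Members without a probe set of their own, among them Isg15 and Ifi44, could not be measured.

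Named genes were, in each comparison with null, the 10 highest and 10 lowest past the threshold whose arrays do not overlap between groups, up to 4 members of each list with the largest change whether or not they passed, Adar, and the sex-linked transcripts; in heterozygous against wild type, the 5 of smallest p. Genes named outside this rule are said to be chosen after their values were seen.

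The method was tested on simulated data with the same groups, in which 50 probe sets each were shifted by 1, 2, 4 or 6 log2 units among 44837 unshifted ones. The test of null against all controls called 42.0%, 60.0%, 92.0% and 98.0% of them and 9 unshifted ones. Against wild type it called 18.0%, 48.0%, 84.0% and 90.0% and 7 unshifted ones, against heterozygous 30.0%, 54.0%, 88.0% and 94.0% and 10, and in heterozygous against wild type 16.0%, 46.0%, 82.0% and 92.0% and 10. A list raised by 1 log2 unit was found (adjusted p = 1.41e-26 and 4.50e-28) with 0 of 73 other list tests called by camera. The simulated probe sets varied independently, so this cannot show how many false list calls correlated genes would give.

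Alternatives were quantile and cyclic loess normalization, a filter at the median level, a pseudocount of 32, trended and robust variance, array weights, models of the 2 compared groups alone, 1 value per gene by brightest or mean probe set, a fold threshold of 2, a covariate for embryo sex, pooled controls, estimated correlation, fry, and leaving out each array. Added after seeing the data were a fit without null array 1 and wild-type array 2, the arrays of lowest correlation in their groups, and a filter to probe sets above background on every array of a group. Also added after seeing the data were an overlap of simulated lists of equal length, the cell type markers under other filters, and the stress arms without members already named. Further hepatocyte and macrophage lists and the split of the stress list into arms served the closing section. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.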

Results

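Gene expression was measured on 8 Affymetrix arrays in haematopoietic stem cells of the fetal liver of C57/B6 mice, sorted for the absence of lineage markers and the presence of Sca-1 and Kit. According to the series' design text, every array holds the cells of 1 mouse. The groups were wild type (2 arrays), heterozygous for the loss of ADAR1 (3 arrays) and ADAR1 null (3 arrays). ADAR1, encoded by Adar, converts adenosine to inosine in double-stranded RNA. Probe sets above background made up 45.6% to 61.2% of those tested on the 5 control arrays (wild type and heterozygous) and 40.0%, 46.4% and 44.7% on the null arrays. The mean log2 intensity of the bacterial spike-in controls was 10.39 to 10.99 on the control arrays and 11.61, 10.73 and 11.54 on the null arrays. The Gapdh 3′ to 5′ intensity ratio, a sign of transcript length in the labelled RNA, was 4.32 to 9.0 on the control arrays and 7.45 to 8.73 on the null arrays. Across probe sets, which are not independent replicates, arrays correlated at 0.915 within wild type, 0.968 to 0.973 within heterozygous and 0.862 to 0.886 within null. Xist, the RNA that silences an X chromosome in females, and the Y-linked Eif2s3y gave a male pattern on heterozygous arrays 1 and 3 and null array 1. The other arrays had a female pattern. The 2 probe sets of Kit, a receptor on which the cells were sorted, read only 6.34 to 23.5 linear units over all arrays. The number of arrays limits the precision of every value given here.

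The Adar transcript was examined before the group comparisons. Its brightest probe set had a mean log2 intensity of 3.54 in wild type, 3.68 in heterozygous and 6.85 ± 0.83 (SD, n = 3) in null cells. It was higher in null cells than in all controls by 3.22 ± 0.41 log2 units (SE), which is 9.35-fold (limma, adjusted p = 0.0170). On the linear scale the null arrays read 59.7, 144 and 176 and the control arrays 7.66 to 17.6. Against wild type alone (3.31 ± 0.55, adjusted p = 0.105) and heterozygous alone (3.17 ± 0.49, adjusted p = 0.0681) the difference did not pass the threshold. The call against all controls was lost without heterozygous array 1 (adjusted p = 0.0630) or 3 (0.0610) and with a pseudocount of 32 (0.0545), over alternatives that ran from 0.00656 to 0.0630. Against heterozygous alone the difference passed the threshold with quantile (0.0357) or cyclic loess normalization (0.0379), a filter at the median level (0.0383), array weights (0.0473), 1 value per gene by brightest (0.0491) or mean probe set (0.0260) and without null array 1 (0.0378), over alternatives from 0.0260 to 0.255. With the mean of all probe sets the differences shrank to 0.96 against wild type, 1.19 against heterozygous and 1.10 against all controls, and with the pseudocount to 1.76, 1.74 and 1.75. On the brightest probe set heterozygous and wild-type cells differed by 0.14 ± 0.55 (adjusted p = 0.985). The other 2 Adar probe sets differed between null and wild type by -0.39 ± 0.36 and -0.04 ± 0.26 log2 units (adjusted p = 0.847 and 0.981). Between heterozygous and wild type they differed by -1.04 ± 0.36 and 0.20 ± 0.26 (limma, adjusted p = 0.891 and 0.940, unadjusted p = 0.0246 and 0.466). The first of them read 13.5 and 12.7 linear units in wild type and 6.02 to 6.74 in heterozygous, near the background of those heterozygous arrays (6.20 to 6.98). The exons removed from the null allele and the positions of the probes are not given in the sources used here, so none of these levels checks the genotype labels.

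**Figure D1:**
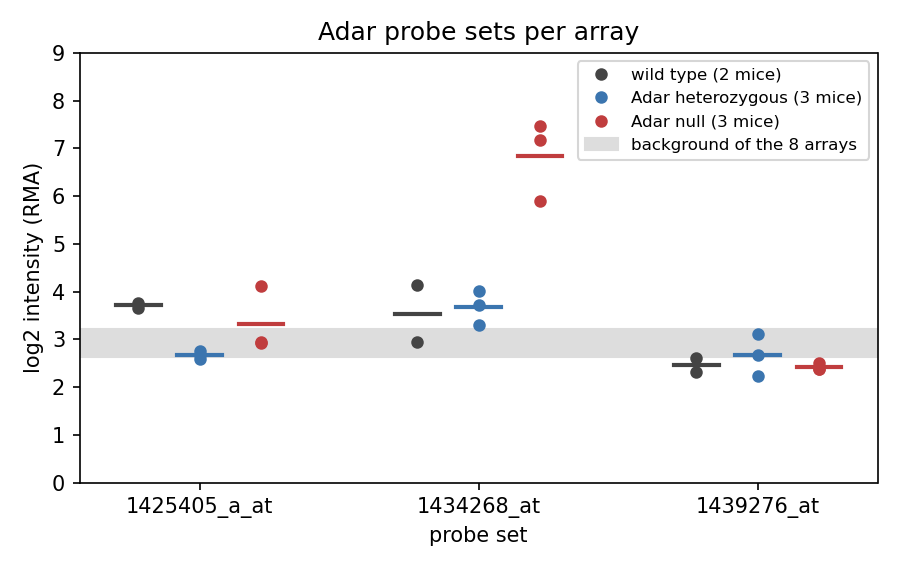
Log2 RMA intensity (vertical axis) of the 3 Adar probe sets on each of the 8 arrays (points), with bars at the means of 2 wild-type, 3 heterozygous and 3 null mice and a grey band over the background of the arrays. On the brightest probe set the null mean is 6.85 and the control mean 3.62.

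Null was compared with wild type to ask which transcripts differ in stem cells that lack ADAR1. Genes known to be induced by type I interferon were among the largest increases. Rsad2 (viperin, an antiviral enzyme) rose 323-fold (8.34 ± 0.58 log2 units, SE; n = 3 null and 2 wild type; adjusted p = 0.00447). Ifit1, which binds foreign RNA, rose 222-fold (7.80 ± 0.62, adjusted p = 0.00722) and the exonuclease Isg20 rose 198-fold (7.63 ± 0.47, adjusted p = 0.00257). Of the 45 measured type I interferon-induced genes, 30 rose over all genes and 41 when adjusted over the list alone, and none fell by either count. Their median difference was 4.74 log2 units, or 4.68 with bounded genes at their bound. The list as a whole rose (camera, adjusted p = 2.51e-74, and adjusted p = 0.0435 with an estimated correlation). A gene whose dimmer group sits at background on every array has no measured level there, so its fold is given as the least it can be, computed against the background.

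Interferon-inducible GTPases, which act against intracellular pathogens, were higher in null than in wild type. Iigp1 rose at least 92.1-fold (adjusted p = 0.00138), Igtp at least 52.5-fold (0.00442) and Irgm2 68.5-fold (0.00557). Gbp7, chosen after its values were seen, rose by 3.89 ± 0.49 log2 units (0.0395). These were the 4 of 18 measured GTPases and interferon-gamma-type targets past the threshold over all genes, and 12 rose when adjusted over the list alone. The list had a median of 3.06, or 2.96 with bounds (camera, adjusted p = 1.11e-16, and adjusted p = 0.0575 with an estimated correlation). Among 14 MHC class I antigen presentation genes, 4 rose over all genes and 10 when adjusted over the list alone. They were the immunoproteasome subunit Psmb9 (6.92 ± 0.76), the class I transactivator Nlrc5 (3.79 ± 0.22) and, chosen after their values were seen, B2m (2.85 ± 0.28) and H2-K1 (2.83 ± 0.21). The MHC class I median was 2.58 (camera, adjusted p = 2.04e-16, and adjusted p = 0.0575 with an estimated correlation). Of 15 interferon ligands, receptors and receptor kinases, 0 passed by limma over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. That list had a median of 0.25, or 0.16 with bounds (camera, adjusted p = 0.352). Ifnb1, the gene of interferon beta, differed by 1.60 ± 0.61 log2 units, at least 2.23-fold, which did not pass (adjusted p = 0.595).

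Stress response genes rose in null against wild type as well. Trib3, a pseudokinase induced under amino acid and endoplasmic reticulum stress, rose at least 48.2-fold (adjusted p = 0.00257). Ddit3, the transcription factor CHOP, rose by 2.86 ± 0.38 log2 units (0.0475). These were the 2 of 24 genes of the unfolded protein and integrated stress response past the threshold over all genes, and 7 rose when adjusted over the list alone. The list median was 0.74, or 0.70 with bounds (camera, adjusted p = 2.42e-06, and adjusted p = 0.0575 with an estimated correlation), and 1.15 without null array 3. Nupr1, a stress-induced nuclear protein, rose by 6.58 ± 0.82 (0.0395) and the ubiquitin ligase Rnf213 by 7.50 ± 0.44 (0.00257).

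Blood lineage genes changed singly rather than as lists in null against wild type. Of 21 myeloid and granulocyte genes, 2 rose over all genes: Plac8 by 5.11 ± 0.43 log2 units (adjusted p = 0.00970) and Csf2rb, a shared chain of cytokine receptors, by 4.31 ± 0.48 (0.0254). Adjusted over the list alone 3 rose and 2 fell, and the list median was 0.01 (camera, adjusted p = 0.765). Gata1, a transcription factor of the erythroid and megakaryocyte lineages, rose by 1.24 ± 0.15 (0.0355) and was the 1 of 26 erythroid genes past the threshold. Adjusted over the list alone 2 erythroid genes rose and 1 fell (median -0.18, camera adjusted p = 0.527). Of 32 stem and progenitor genes, 0 passed by limma over all genes or adjusted over the list alone, and 4 were higher and 2 lower at an unadjusted p under 0.05 (median -0.15, or -0.11 with bounds; camera adjusted p = 0.596).

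Transcripts lower in null than in wild type came from many functions. Plec, a linker of the cytoskeleton, fell by 3.86 ± 0.36 log2 units (adjusted p = 0.0121), the translation initiation factor Eif2d by 3.47 ± 0.42 (0.0371) and the splicing helicase Dhx38 by 3.30 ± 0.37 (0.0266). Plec was also low in heterozygous cells, with group mean log2 intensities of 6.95 in wild type, 3.50 in heterozygous and 3.09 in null. Proliferation genes fell as a list, with 27 of 31 lower and a median of -0.68 (camera, adjusted p = 1.05e-06, and adjusted p = 0.202 with an estimated correlation). By limma 0 proliferation genes passed over all genes or adjusted over the list alone, and 9 were lower at an unadjusted p under 0.05. Cholesterol biosynthesis genes were lower in 16 of 18, with a median of -0.88 (camera, adjusted p = 0.0250, and adjusted p = 0.258 with an estimated correlation). By limma 0 of them passed on either count and 2 were lower unadjusted. This call was lost without wild-type array 1 (median -0.55, adjusted p = 0.321), null array 1 (median -0.44, 0.122) or null array 2 (0.0645). It was also lost with cyclic loess (0.0595), the filters at the median level (0.111) and above background (0.156), the mean of probe sets (median -0.28, 0.205) and fry (0.105), over alternatives from 0.00942 to 0.321. Housekeeping genes fell with these lists at a median of -0.71 (camera, adjusted p = 0.00249, and adjusted p = 0.365 with an estimated correlation), a call lost without wild-type array 2 (median -0.37, 0.0827), without that array and null array 1 (median -0.16, 0.276) and with fry (0.128). Without null array 3 the housekeeping median was -0.38 (0.0103). Fry also left the proliferation call out (0.0823). Of 10 housekeeping genes 0 passed over all genes by limma, and 3 fell both when adjusted over the list alone and at an unadjusted p under 0.05.

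Markers of other cells in the fetal liver were examined in the same comparison. Of 19 hepatocyte and hepatoblast genes, 0 passed over all genes by limma. Afp, Alb and Apoa2, at -4.11 ± 0.84, -3.09 ± 0.48 and -1.76 ± 0.42 log2 units, were the 3 that fell when adjusted over the list alone and the 3 lower at an unadjusted p under 0.05. The list median was -0.10, or -0.04 with bounds (camera, adjusted p = 0.0822). It passed with the mean of probe sets (0.0460), the sex covariate (0.0459) and the filter above background (median -1.07, 0.0288), over alternatives from 0.0288 to 0.537. Of 18 macrophage genes, 0 passed over all genes, and 5 were lower and 1 higher at an unadjusted p under 0.05. The complement gene C1qb (-4.22 ± 0.81) alone fell when adjusted over the list alone, and the list median was -0.22 (camera, adjusted p = 0.146). The macrophage list passed with the filters at the median level (median -0.83, 0.0448) and above background (median -0.96, 0.00705), over alternatives from 0.00705 to 0.462. Endothelial and stromal genes (16 measured) had a median of -0.03 (0.918), with 2 higher and 2 lower unadjusted. The medians were 0.05 for 16 lymphoid progenitor genes (0.560), 0.09 for 16 megakaryocyte genes (0.275) and 0.12 for 11 mast cell genes (0.110), with 0, 1 and 1 members higher unadjusted and none lower. The megakaryocyte list passed with cyclic loess (median 0.29, 0.0306). In these 4 lists limma called 0 members over all genes or adjusted over the list alone.

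Limma called 0 members over all genes in the 8 lists not yet given for null against wild type. Of 26 cell death effectors and regulators, 4 rose and 1 fell when adjusted over the list alone, and 8 were higher and 3 lower unadjusted (median 0.22, or 0.16 with bounds; camera adjusted p = 0.0662). That list passed without wild-type array 2 (0.0466) or null array 3 (0.0463) and with quantile (median 0.41, 0.0411) or cyclic loess normalization (median 0.36, 0.0354), over alternatives from 0.0354 to 0.326. Of 22 p53 targets, 2 rose and 2 fell when adjusted over the list alone, and 3 were higher and 3 lower unadjusted (median 0.09, adjusted p = 0.523). Of 8 A-to-I editing enzymes and relatives, Adar alone rose when adjusted over the list alone, as it did unadjusted (median 0.06, adjusted p = 0.303). No member of the other 5 lists passed when adjusted over the list alone. The 49 neighbours of Adar on chromosome 3 had a median of -0.09 (adjusted p = 0.591), with 1 higher and 5 lower unadjusted. The 23 NF-kappaB targets and inflammatory cytokines had a median of 0.14 (0.390), with 1 lower unadjusted. The 35 cytosolic ribosomal proteins had a median of 0.00 and a mean of -0.07 and were tested as lower (0.825), with 2 higher and 2 lower unadjusted. The 15 transcripts with known A-to-I recoding sites had a median of -0.02 and a mean of 0.15 and were tested as higher (0.637), with 0 under an unadjusted p of 0.05. The 4 sex-linked transcripts had a median of 0.18 (0.08 with bounds) and a mean of -0.04 and were tested as lower (0.961), also with 0.

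In all, 147 of 45037 probe sets differed between null and wild type by limma, 99 higher and 48 lower, and 3437 had an unadjusted p under 0.05. By brightest probe set 71 genes rose and 23 fell. Of the named genes past the threshold, 11 of 17 higher ones and 1 of 10 lower ones, Igsf8 (-2.45 ± 0.22), stayed past it without each array in turn. Among the higher ones that did not, Gata1 lost the call without each of the 8 arrays (adjusted p up to 0.107), and Ddit3 without all but wild-type array 1 (up to 0.138). Nupr1 lost it without all but wild-type array 2 (up to 0.101), Ifit3 and Csf2rb without each of the 5 control arrays (up to 0.0665 and 0.0779), and Psmb9 without 6 arrays (up to 0.0834). The lower ones reached at most 0.0566 (Plec) to 0.142 (Zdhhc24), and each of the 8 arrays ended at least 1 of these calls. With the arrays of the 2 groups alone 4 probe sets passed, all higher, 62 did with a pseudocount of 32, 90 with array weights and 79 with the sex covariate. The number of probe sets past the threshold was 340 without wild-type array 1, 239 without null array 2, and 65, 90 and 68 without heterozygous arrays 1, 2 and 3.

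Null was also compared with heterozygous, the group with 1 intact allele and as many arrays. Antiviral genes were again among the largest increases, with Rsad2 279-fold higher (8.13 ± 0.52 log2 units, SE; n = 3 and 3; adjusted p = 0.00268), Ifit1 225-fold (7.81 ± 0.55, 0.00376) and Isg20 139-fold (7.12 ± 0.42, 0.00193). Usp18, the protease that removes ISG15 from proteins, rose at least 78.4-fold (0.000385), Iigp1 at least 106-fold (0.000671) and the chemokine Cxcl10 at least 42.3-fold (0.0290). Of the 45 type I interferon-induced genes, 35 rose over all genes and 43 when adjusted over the list alone. Their median was 4.44, or 4.42 with bounds (camera, adjusted p = 2.08e-60, and adjusted p = 0.0435 with an estimated correlation). Interferon-inducible GTPases and interferon-gamma-type targets rose in 7 of 18 over all genes and in 13 adjusted over the list alone. Their median was 3.59, or 3.36 with bounds (camera, adjusted p = 7.98e-15, and adjusted p = 0.0626 with an estimated correlation). MHC class I genes rose in 4 of 14 and in 11 adjusted over the list alone, with a median of 2.12 (camera, adjusted p = 3.12e-11, and adjusted p = 0.0626 with an estimated correlation). Stress response genes rose as a list, with Trib3 (5.65 ± 0.33, 0.00187) and Ddit3 (2.58 ± 0.34, 0.0358) the 2 past over all genes, and 5 higher and 1 lower adjusted over the list alone. Their median was 0.56 (camera, adjusted p = 0.00176, and adjusted p = 0.144 with an estimated correlation), and the call was lost without null array 2 (median 0.37, 0.0681). Without null array 3 the stress median was 0.91.

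Hepatocyte and macrophage genes were lower in null than in heterozygous cells. Afp, the fetal serum protein alpha-fetoprotein, fell by 5.78 ± 0.75 log2 units (adjusted p = 0.0354) and the apolipoprotein Apoa2 fell by 3.32 ± 0.37 (0.0223). These were the 2 of 19 hepatocyte and hepatoblast genes past over all genes, and 5 fell when adjusted over the list alone. The list median was -0.53 (camera, adjusted p = 0.000169, and adjusted p = 0.258 with an estimated correlation), and -0.17 without heterozygous array 1 (0.0197). Macrophage genes fell as a list, with a median of -0.29, or -0.19 with bounds (camera, adjusted p = 0.0250, and adjusted p = 0.258 with an estimated correlation). Of 18 members 0 passed over all genes by limma, 3 fell adjusted over the list alone, and 4 were lower and 1 higher at an unadjusted p under 0.05. The macrophage call was lost without heterozygous array 1 (median -0.17, adjusted p = 0.0744), null array 2 (0.0896) or null array 3 (0.0580), with the sex covariate (0.0663) and with fry (0.0615). Fry also left the hepatocyte call out (0.0737). Maf, a transcription factor, fell at least 6.84-fold (0.00493). The Afp call was lost without each heterozygous array and without null arrays 2 and 3 (up to 0.169), and the Apoa2 call without heterozygous arrays 1 and 3 and null arrays 1 and 3 (up to 0.119).

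**Figure D2:**
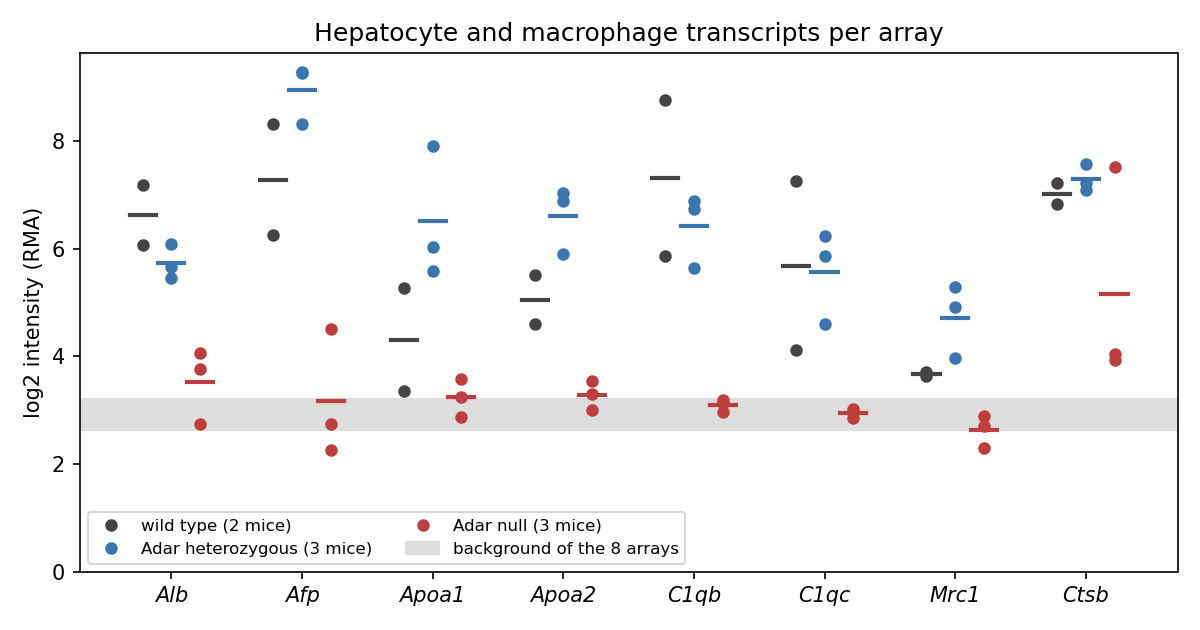
Log2 RMA intensity (vertical axis) of 4 hepatocyte genes (Alb, Afp, Apoa1, Apoa2) and 4 macrophage genes (C1qb, C1qc, Mrc1, Ctsb) on each array (points), with bars at the means of 2 wild-type, 3 heterozygous and 3 null mice and a grey band for background. Afp has group means of 7.29, 8.96 and 3.18, and C1qb of 7.31, 6.42 and 3.09.

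Erythroid and growth-related lists were also lower in null than in heterozygous cells. Erythroid genes fell as a list, with a median of -0.45, or -0.37 with bounds (camera, adjusted p = 0.0291, and adjusted p = 0.202 with an estimated correlation). By limma 0 of 26 passed over all genes, 3 fell adjusted over the list alone, and 7 were lower and 1 higher unadjusted. The erythroid call was lost with quantile (median -0.26, 0.153) or cyclic loess normalization (median -0.11, 0.392), the filters at the median level (0.355) and above background (0.225) and fry (0.0849). It was also lost without heterozygous array 1 (0.0517), null array 1 (median -0.12, 0.0508) or null array 2 (median -0.30, 0.0899), and the median was -0.69 without null array 3 (0.00914), over alternatives from 0.00914 to 0.392. Proliferation genes fell at a median of -0.84 (camera, adjusted p = 3.16e-09, and adjusted p = 0.151 with an estimated correlation). Ccne1, cyclin E1, fell by 2.06 ± 0.22 log2 units (0.0166) and was the 1 of 31 past over all genes, and 4 fell adjusted over the list alone. Cholesterol biosynthesis genes fell at a median of -0.70 (camera, adjusted p = 0.000323, and adjusted p = 0.151 with an estimated correlation), with 0 of 18 past by limma on either count and 5 lower unadjusted. Housekeeping genes fell at a median of -0.72 (camera, adjusted p = 0.000169, and adjusted p = 0.258 with an estimated correlation). Gusb, a lysosomal enzyme, fell by 2.48 ± 0.30 (0.0277) and was the 1 of 10 past over all genes, and 3 fell adjusted over the list alone. With fry the cholesterol and housekeeping calls were lost, each at 0.0625. The Ccne1 call was lost without each heterozygous array (up to 0.0904) and the Gusb call without all but null arrays 2 and 3 (up to 0.123).

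Cytosolic ribosomal proteins had a median of -0.11 in null against heterozygous (camera, adjusted p = 0.0499, and adjusted p = 0.243 with an estimated correlation). By limma 0 of 35 ribosomal proteins passed on either count and 4 were lower unadjusted. The ribosomal call was lost without each of the 8 arrays in turn (adjusted p from 0.0580 without null array 3 to 0.120 without null array 1, where the median was -0.06). It was also lost with quantile normalization (median -0.01, 0.824), the filters at the median level (0.753) and above background (0.807), the sex covariate (0.0549) and fry (0.0625). The median was 0.07 with cyclic loess normalization (0.376). Among single genes, Eif2d fell by 3.99 ± 0.38 log2 units (adjusted p = 0.0119), Aph1a, a subunit of gamma-secretase, fell at least 10.5-fold (0.0261), and Gatb, a subunit of a mitochondrial tRNA amidotransferase, fell by 3.35 ± 0.37 (0.0213). The Eif2d call was lost without heterozygous arrays 1 and 3 (up to 0.0700).

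The remaining lists did not pass in null against heterozygous, though cell death genes did with cyclic loess (median 0.35, 0.0488) and the filter above background (median 0.13, 0.0444). Of 21 myeloid and granulocyte genes 3 rose: Csf2rb by 4.31 ± 0.43 log2 units (adjusted p = 0.0136), Plac8 by 3.40 ± 0.38 (0.0223) and, chosen after its values were seen, Spi1 by 1.81 ± 0.24 (0.0384). The myeloid list itself had a camera adjusted p of 0.481. Cyfip2, a cytoskeletal regulator with a known recoding site, fell at least 3.43-fold (0.0165). Its call was lost without heterozygous array 1 or 3 or null array 1 (adjusted p up to 0.0891). Neither against wild type nor against all controls did Cyfip2 reach an unadjusted limma p under 0.05. Its list of recoding-site transcripts had a median of 0.14 and a mean of -0.13 and was tested as higher (0.848). The medians and means also differed in sign for interferon ligands and receptors (0.01 and -0.06, tested as higher, 0.845), stem and progenitor genes (0.03 and -0.19, tested as lower, 0.481) and megakaryocyte genes (-0.05 and 0.14, tested as higher, 0.961). The p53 targets had a median of 0.08 and a mean of 0.00 and were tested as lower (0.752).

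In all, 226 probe sets differed between null and heterozygous by limma, 118 higher and 108 lower, and 5106 had an unadjusted p under 0.05. By brightest probe set 83 genes rose and 57 fell. Of the probe sets higher against wild type, 89 were also higher against heterozygous, where unrelated lists would share 0.259. Of those lower, 30 were also lower, where unrelated lists would share 0.115, and none changed in opposite directions. Both comparisons use the same 3 null arrays, which alone makes their smallest p fall together. In 20 simulations without any change, the probe sets of smallest p, taken in the same numbers, shared a mean of 18.9 higher (10 to 28) and 12.35 lower (7 to 18) ones, so part of the overlap may come from the shared arrays. Of the named genes past the threshold, 10 of 17 higher ones and 1 of 13 lower ones, Maf, stayed past it without each array in turn. For the others the adjusted p rose to between 0.0576 and 0.186, and each of the 8 arrays ended at least 1 call. The count of probe sets was 126 with a pseudocount of 32, 130 with trended and robust variance and 105 with the sex covariate. The number past the threshold was 581 without null array 2, and 63, 73 and 82 without heterozygous arrays 1, 2 and 3.

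The comparison of heterozygous with wild type asked whether loss of 1 allele alters expression. Interferon-induced genes did not separate these groups. By limma 0 of 45 passed over all genes or adjusted over the list alone, and 3 were higher and 1 lower at an unadjusted p under 0.05. The list had a median of -0.02 and a mean of 0.02 (camera, tested as higher, adjusted p = 0.503). A single probe set without a gene name, chosen after its values were seen, fell by 3.44 ± 0.19 log2 units (SE; n = 3 and 2; adjusted p = 0.0278), and 2418 probe sets had an unadjusted p under 0.05, beside 2252 by chance. The transcripts of smallest p with a gene name did not pass. Among them were Wasf1, a regulator of actin (-2.32 ± 0.21, adjusted p = 0.130), Plec (-3.46 ± 0.36, 0.187), the kinase Cilk1 (-2.61 ± 0.26, 0.187) and Suds3 (1.89 ± 0.19, 0.187). The number of probe sets past the threshold was 164 without wild-type array 1 and 38 without wild-type array 2, each of which leaves a lone wild-type array assumed to vary like the other groups.

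Gene lists higher in heterozygous than in wild-type cells numbered 5 by camera, each with 0 members past the threshold over all genes by limma. Hepatocyte genes had a median of 0.17, or 0.11 with bounds (adjusted p = 0.0154, and adjusted p = 0.462 with an estimated correlation), with 4 higher unadjusted and 1 adjusted over the list alone. Erythroid genes had a median of 0.27 (adjusted p = 0.0398, and adjusted p = 0.202 with an estimated correlation), with 6 higher and 1 lower unadjusted and 4 higher adjusted over the list alone. Ribosomal proteins had a median of 0.06 (adjusted p = 0.0330, and adjusted p = 0.202 with an estimated correlation), with 0 under an unadjusted p of 0.05. Stress response genes had a median of 0.20 (adjusted p = 0.0444, and adjusted p = 0.255 with an estimated correlation) and MHC class I genes of 0.22 (adjusted p = 0.0499, and adjusted p = 0.462 with an estimated correlation), each with 1 higher unadjusted. Without wild-type array 1 the 5 calls were lost, at adjusted p of 0.237, 0.298, 0.233, 0.187 and 0.118, and without heterozygous array 1 at 0.235, 0.0782, 0.0549, 0.0662 and 0.0744. Each of the other arrays ended at least 1 of them. The hepatocyte median turned to -0.04 without heterozygous array 1 and to -0.01 with the sex covariate, and it was 0.34 without either wild-type array and 0.28 without heterozygous array 2. The erythroid median was 0.17 without heterozygous array 2 and 0.47 without heterozygous array 3. The ribosomal median was 0.11 without wild-type array 2 and 0.12 without heterozygous array 3. The stress median was 0.13 without wild-type array 1, and the MHC class I median 0.11 without wild-type array 2. Fry left all 5 out (0.117 to 0.420). Both normalizations and the filter at the median level ended all but the hepatocyte call, which was lost with the sex covariate (0.272).

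Null was finally compared with all 5 controls together. Interferon-induced genes stood apart in every null mouse, with a mean over the list 4.42 ± 0.39 log2 units above the control mean (SD, n = 3; 21.3-fold), where the 5 controls had an SD of 0.03. The two-sided exact permutation p was 0.0179, the smallest that 56 splits allow (adjusted p = 0.0406 over 25 lists). Of its 45 genes 37 rose over all genes and 43 adjusted over the list alone, with Rsad2 at 8.21 ± 0.44 (SE, adjusted p = 0.000190) and Usp18 at 6.42 ± 0.24 (5.08e-05). Scores of interferon-inducible GTPases were higher by 2.88 ± 0.43 (SD), of MHC class I genes by 2.28 ± 0.44 and of stress response genes by 0.98 ± 0.23, each at the same exact p of 0.0179. Of their members 8 of 18, 5 of 14 and 3 of 24 rose over all genes, and 13, 12 and 9 adjusted over the list alone, where 2 stress genes also fell. Igtp rose at least 57.1-fold (0.000166), Nlrc5 by 3.72 ± 0.17 log2 units (0.000135), Trib3 by 5.81 ± 0.30 (0.000166) and Ddit3 by 2.69 ± 0.29 (0.00767). Atf4, the transcription factor that drives the integrated stress response, was the third stress gene and, chosen after its values were seen, rose by 1.09 ± 0.14 (0.0170).

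Cell type and growth lists had lower scores in the null mice. Scores of hepatocyte genes (-0.99 ± 0.12, SD), macrophage genes (-0.75 ± 0.05), erythroid genes (-0.46 ± 0.15), proliferation genes (-0.85 ± 0.37) and cholesterol genes (-0.81 ± 0.44) each reached the exact permutation p of 0.0179 (n = 3 and 5, adjusted p = 0.0406). Random lists matched on expression also fell, with means of -0.28 beside the erythroid list, where 1067 of 10000 were as low, -0.44 beside proliferation (13 as low) and -0.28 beside cholesterol (17 as low). Of 26 erythroid genes 0 passed over all genes by limma, 1 fell adjusted over the list alone, and 4 were lower and 1 higher unadjusted. Cell death genes (0.24 ± 0.20) and mast cell genes (0.22 ± 0.08) had higher scores at the same exact p, where 72 and 1212 of 10000 matched random lists were as high. Of 26 cell death genes 1 rose over all genes, and 6 rose and 3 fell adjusted over the list alone. Of 11 mast cell genes, 4 of them at background in all groups compared, 0 passed by limma on either count and 1 was higher unadjusted. Afp was the 1 of 19 hepatocyte genes past over all genes (-5.11 ± 0.79, SE, adjusted p = 0.0403), and 3 fell adjusted over the list alone. The hepatocyte median was -0.62, or -0.18 with bounds. Of 18 macrophage genes 0 passed over all genes by limma, 4 fell and 1 rose adjusted over the list alone, and 6 were lower and 1 higher unadjusted. By limma 0 of 31 proliferation genes passed over all genes, 9 fell adjusted over the list alone and 17 were lower unadjusted, and 0 of 18 cholesterol genes passed on either count with 3 lower unadjusted.

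Some single genes of other lists also passed in null against all controls. Housekeeping genes scored -0.78 ± 0.40 (SD, exact permutation p = 0.0357, adjusted p = 0.0744), with Gusb the 1 of 10 that fell (-2.15 ± 0.34, SE, limma adjusted p = 0.0469), and 685 of 10000 matched random lists were as low. Ribosomal proteins scored -0.15 ± 0.11 (exact permutation p = 0.0714), above most matched random lists, of which 9973 of 10000 were as low (mean -0.42). Lyz2, lysozyme, fell by 2.54 ± 0.34 log2 units (0.0207). The necroptosis effector Mlkl rose by 2.78 ± 0.41 (0.0349) and Csf2rb by 4.31 ± 0.36 (0.00207). Stem and progenitor genes scored -0.20 ± 0.30 (exact permutation p = 0.232), and of the 32 measured 0 passed by limma, with 2 higher and 7 lower unadjusted.

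**Figure D3:**
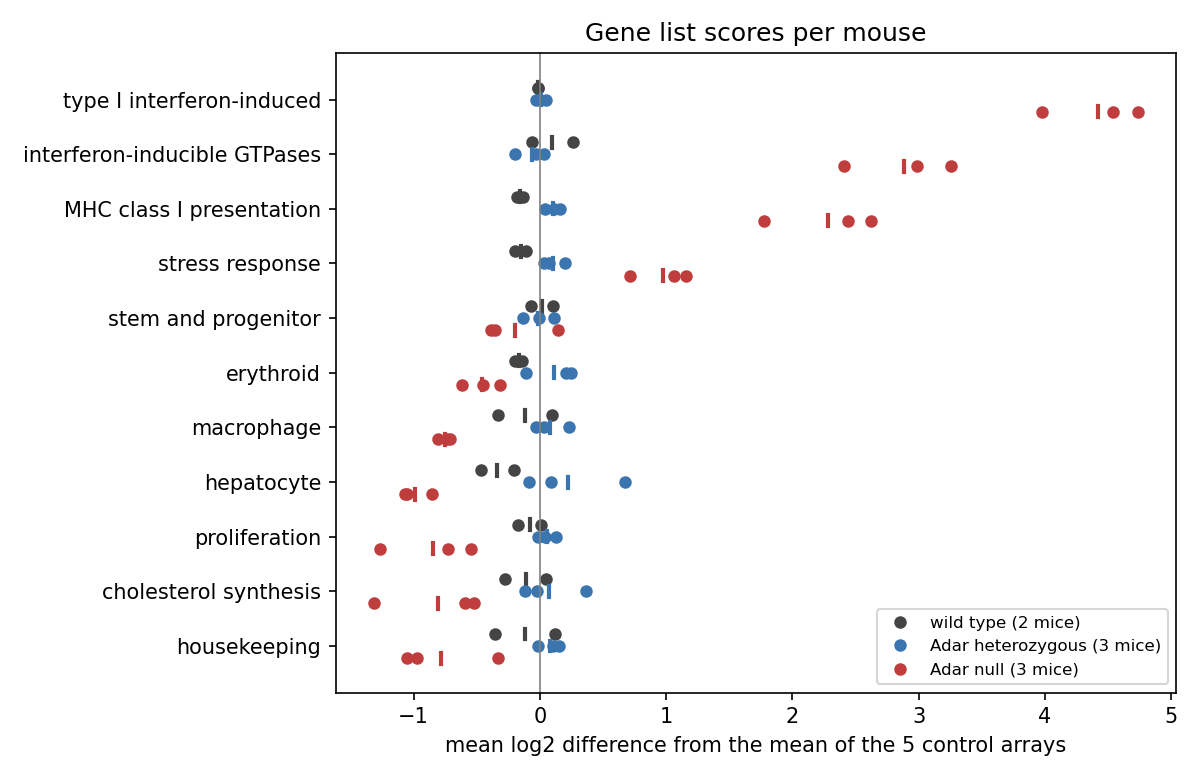
Mean log2 difference from the mean of the 5 control arrays (horizontal axis) for 11 gene lists, where each dot is 1 mouse (2 wild type, 3 heterozygous, 3 null) and vertical ticks are group means. The null mice average 4.42 on the type I interferon list and -0.99 on the hepatocyte list.

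In all, 262 probe sets differed between null and all controls by limma, 148 higher and 114 lower, and 5190 had an unadjusted p under 0.05. Of the named genes past the threshold, 17 of 20 higher ones and 2 of 12 lower ones, Eif2d (-3.78 ± 0.35) and the ubiquitin ligase Rnf145 (-3.22 ± 0.36), stayed past it without each array in turn. The adjusted p rose to 0.0630 for Adar, 0.122 for Afp, 0.135 for Gusb, 0.107 for Mlkl and 0.0733 for Lyz2, and each of the 8 arrays ended at least 1 call. The number of probe sets past the threshold was 792 without null array 2, 409 without null array 3, and 156, 170 and 168 without heterozygous arrays 1, 2 and 3.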

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

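The tests of the interferon genes, of fewer macrophages or hepatocytes among the null cells and of other filters on their genes were chosen only after the result was seen. So were those of single lists against a shared shift and of lower signal on null arrays 1 and 3. The tests of other splits were not. The test of a shared shift for pooled lower lists was fixed before it was run, but its lists were picked because they were lower. Random lists were not picked in that way, so a small number of them as low is partly fixed by that choice. Outside the genes tested, the array's control probe set for the mouse B2 repeat was brighter on the null arrays, at 13.58 ± 0.03 (SD, n = 3) against 13.43 ± 0.04 log2 units on the 5 control arrays. The difference was 0.15 log2 units. Its two-sided exact permutation p of 0.0179, the smallest that 56 splits allow, carries no weight. The probe set was picked because all null arrays lay above all controls. Of the 64 control probe sets, 4 had all null arrays above all controls, where chance gives 1.14, and the other 3 of them were at background.

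Type I interferon-induced genes were higher on all 3 null arrays, by 4.42 ± 0.39 log2 units. A shift shared by genes of like expression level would raise matched random lists as far, but the highest of 10000 reached 0.50. Macrophages in the null sort would raise the macrophage list, which instead stood at -0.75 ± 0.05 (SD, n = 3). The sort against lineage markers gives no further argument, since the macrophage gene C1qb read 5.64 to 8.76 on the control arrays, above background. Sex of the embryos would leave no difference among arrays of the female pattern, yet there the score differed by 4.36 (2 null and 3 control arrays, control SD 0.01). The loss of ADAR1, by which the groups were defined, is a candidate explanation. The gene list and the comparison were fixed before the data were examined, while the other explanations were tested after the result was seen. Loss of ADAR1 stays a hypothesis because litter and day of sorting are not given in the sources used here and could not be told apart from it.

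Of the hepatocyte and macrophage genes, 16 were above background on every control array. Each of the 16 had a lower mean over the null arrays than over the pooled control arrays. Their mean difference was -1.73 ± 0.16 (SD, n = 3), and 4 were at background on all null arrays. Single arrays overlapped between null and controls for most of the 16, namely Apoa1, Cd68, Ctsb, Dlk1, Hmox1, Marco, Mpeg1, Rbp4 and Timd4. Only Afp, Alb, Apoa2, C1qb, C1qc, Mrc1 and Ttr had all null arrays below all control arrays. Ctsb on null array 2 read 7.52, within the control range (6.83 to 7.57). Dlk1 read 3.24 to 4.44 on the null arrays and 3.04 and 3.26 in wild type. Hmox1 read 3.40 to 4.68 on the null arrays and 3.09 and 4.30 in wild type. All 37 measured members of both lists gave -0.87 ± 0.07 (27 lower, 10 higher). Of 10000 matched random lists 0 were as low (lowest -0.84, or -0.88 when drawn only from genes above background on every control array). This argues against a shift shared by all genes of like expression level, though less than the count implies. Both lists were picked for being low and the random ones were not. Fewer macrophages among the sorted null cells may account for their part. Of 22 measured genes of a further macrophage list, 6 were above background on every control array. All 6 were lower, by -1.30 ± 0.11 (highest null -1.18, lowest control -0.35, exact permutation p = 0.0179). Under the same filter 2 of 10000 random lists were as low. No gene joined when the null arrays could also admit it. That check is weak, because null arrays 1 and 3 had fewer probe sets above background than any control array. All 22 gave -0.44 ± 0.03 (15 lower, 7 higher, exact p = 0.0536). C1qb fell from means of 7.31 and 6.42 in wild type and heterozygous to 3.09, but as a member of the first list it is no separate evidence. Fewer hepatocytes cannot be told apart from other sources, because only 2 of 24 measured genes of a further hepatocyte list were above background on every control array (mean difference 0.00788; all 24 gave -0.04 ± 0.08, with 12 lower and 12 higher); both cell types had been 1 test until it gave no verdict, and were split, with a minimum of 3 genes, afterwards. In all groups the sort should remove macrophages by their lineage markers and hepatocytes by the demand for Sca-1 and Kit. Yet Afp read 6.25 to 9.28 and C1qb 5.64 to 8.76 on the control arrays, where background was at most 3.03. Whether other cells passed the sort was not tested, and a change of these genes within the stem cells stays open as untested.

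Proliferation, cholesterol and housekeeping genes were lower on the null arrays, by a mean of -0.82 over 59 genes. Matched random lists also fell, to a mean of -0.39 and a lowest of -0.82, and 0 of 10000 were as low, though the lowest equals the observed mean at 2 decimals. Taken alone, proliferation and cholesterol genes had 13 and 17 random lists as low, which argues against a shift shared by all genes of like expression level as their whole cause. These counts overstate the evidence, because random lists leave out correlation among the genes of a list. The lists were also picked for being low, and the random ones were not. With an estimated correlation camera gave adjusted p = 0.202 and 0.258 for the 2 lists in null against wild type. Housekeeping genes had 685 random lists as low, so such a shift could account for their part. Lower signal on null arrays 1 and 3 would leave null array 2 within the control range. Over the pooled lists null array 2 stood at -0.60, below the controls (-0.16 to 0.20) but above null arrays 1 and 3 (-1.24 and -0.63). On proliferation genes it read -0.72, below null array 3 (-0.55) and the lowest control (-0.17). On cholesterol genes it read -0.52 (lowest control -0.28). On housekeeping genes it read -0.33, within the control range (lowest -0.36). Because this rests on null array 2 alone, lower signal as part of the cause cannot be told apart from a change in the cells. Slower growth of the null stem cells was not tested apart from these.

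Other splits of the arrays bear on the number of probe sets past the threshold. For null against all controls, the real split, with 262, was the 1 of 56 with as many, and the highest of the others gave 8. This argues against chance but does not exclude it, because a share of 0.0179 is the smallest that 56 splits allow. For null against heterozygous, fitted on the arrays of both groups alone, 10 splits are too few for a share under 0.05; the real split was the 1 with as many, at 201, and the highest other gave 0.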

How the results depend on the processing

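The fit without null array 1 and wild-type array 2 and the filter to probe sets above background on every array of a group were chosen after the result was seen. No paired analysis was possible because replicates were numbered by order of deposit and nothing matches a null mouse to a control. Models of the 2 compared groups alone have no counterpart for null against all controls. Over the settings that apply, the 7 main results kept their value or side of the threshold in 97 cases and changed in 44, where 42 were counts moved by over 1.5 times. Gene lists kept their side of the threshold without a reversal in 1287 cases, with 120 calls lost, 16 gained and 2 reversed. Named genes did so in 5965 cases, with 453 calls lost, 127 gained and 0 reversed. A change of direction counted as reversed only where the result passed the threshold in the main fit or the alternative. Where it passed in neither, the case counted as kept, so these counts do not show how often direction held. The causes were not tested except where fewer arrays or genes are the change itself. Signal over background limits what can be read: between 40.0% and 61.2% of probe sets exceeded it, and folds from background are lower bounds.

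With a pseudocount of 32, which shrinks dim probe sets, null against wild type gave 62 probe sets (57 shared with the 147), null against heterozygous 126 (118 shared with the 226) and heterozygous against wild type 5. Trended and robust variance gave 130 in null against heterozygous (124 shared; 102 higher, 28 lower) and 90 higher and 11 lower in null against wild type and 149 and 49 in null against all controls, array weights 90 in null against wild type (89 shared; 74 higher, 16 lower) and 131 higher and 68 lower in null against all controls, and the sex covariate 79 (74 shared), 105 (95 shared) and 0 in null against wild type, null against heterozygous and heterozygous against wild type; the cause was not tested. Models of the 2 groups alone, with fewer arrays, gave 4 in null against wild type and 0 in heterozygous against wild type, where 4050 had an unadjusted p under 0.05. Pooling the controls gave 262 (121 shared). Heterozygous against wild type by limma gave 0 above the median level (1149 unadjusted), 0 by brightest probe set (954), 0 by the mean of probe sets (988) and 0 above background (1287), and 2360 were unadjusted with the sex covariate. Without null array 1 and wild-type array 2 it gave 38, and null against wild type 197, of which 72 were higher and 125 lower and 51 were shared with the 147.

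Scaling moved the split too, from 99 higher and 48 lower against wild type, 118 and 108 against heterozygous and 148 and 114 against all controls. Quantile normalization gave 111 higher and 37 lower against wild type, 133 and 58 against heterozygous and 180 and 66 against all controls; cyclic loess gave 120 and 31, 143 and 43, and 200 and 54. Cytosolic ribosomal proteins reversed direction under cyclic loess. In null against wild type camera called them lower without passing the threshold (median 0.00135, adjusted p = 0.825) and under cyclic loess higher (median 0.20, adjusted p = 0.0416, in a range of 0.0416 to 0.998 over the alternatives). In null against heterozygous the median went from -0.11 (adjusted p = 0.0499) to 0.0704 (0.376, in a range of 0.00226 to 0.824); the cause was not tested. Estimated correlation left 2 list calls and fry 9, of 23.

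Leaving out each array in turn gave 65 to 340 probe sets in null against wild type, 63 to 581 in null against heterozygous, 0 to 164 in heterozygous against wild type and 156 to 792 in null against all controls. List calls ran from 14 (without null array 2; 15 without heterozygous array 1) to 21. Adar in null against wild type ran from 2.71 to 3.91 without single arrays, was 0.96 with the mean of all probe sets and 1.76 with the pseudocount, and was 4.38 without null array 1 and wild-type array 2 (adjusted p = 0.0341, in a range of 0.0341 to 0.507 over its alternatives). The interferon score ran from 4.26 to 4.64 without single arrays (exact permutation p = 0.0286 or 0.0476), was 4.35 without null array 1 and wild-type array 2, where 0.0667 is the smallest exact p, and 2.82 with the pseudocount to 4.77 above background elsewhere.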

Other observations

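The test of the stress response arms was chosen only after the result was seen. So were the genes outside the lists named here, except Ndufa3 and Sdhaf1. The rule for named genes picked Ndufa3 in null against all controls and Sdhaf1 in null against wild type. Of 170 genes past the threshold in null against all controls by brightest probe set, 62 belonged to a gene list and 108 did not, 43 of them higher and 65 lower. Among the higher ones the Schlafen gene Slfn5 rose at least 46.6-fold (limma, adjusted p = 1.28e-05) and Slfn2 by 3.78 ± 0.22 log2 units (SE; n = 3 and 5; 0.000326). The RNA helicase gene Ddx60 rose by 4.75 ± 0.32 (0.000619) and Oas1c, of the oligoadenylate synthetase family, at least 21.9-fold (0.00214). The cytidine deaminase genes Apobec1 and Apobec3 rose by 3.47 ± 0.43 (0.0154) and 2.45 ± 0.39 (0.0456). Pml, which organizes nuclear bodies, rose by 2.56 ± 0.30 (0.0109), the immediate early gene Egr1 by 3.38 ± 0.47 (0.0265) and the kinase gene Pim1 by 1.92 ± 0.23 (0.0124). The noncoding host genes Zfas1 and Snhg1 rose by 1.49 ± 0.23 (0.0396) and 1.19 ± 0.16 (0.0206).

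Among the lower genes outside the lists were several for mitochondrial proteins. The complex I subunits Ndufa3, Ndufb3 and Ndufs1 fell by 3.04 ± 0.49, 1.75 ± 0.16 and 1.73 ± 0.21 log2 units (limma, adjusted p = 0.0484, 0.00360 and 0.0142). The Ndufa3 call was lost without each of 6 arrays in turn (adjusted p up to 0.140). Sdhaf1, an assembly factor of complex II, fell by 2.61 ± 0.26 (0.00479). The chromatin remodelling gene Arid1a fell by 1.94 ± 0.17 (0.00245) and the topoisomerase gene Top1 by 1.81 ± 0.27 (0.0375). Dut, which keeps uracil out of DNA, fell by 1.11 ± 0.17 (0.0399) and Tipin, a replication fork protein, by 1.12 ± 0.15 (0.0223). The iron exporter gene Slc40a1 fell by 1.74 ± 0.22 (0.0168) and Uros, of haem synthesis, by 1.38 ± 0.14 (0.00588). These genes were not tested as groups.

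Stress response genes were split into the targets of Atf4 and the chaperones of the endoplasmic reticulum, to ask whether the Atf4 arm alone rises. The 15 Atf4 targets, 14 of them higher, stood at 1.55 ± 0.44 log2 units in null mice (SD, n = 3; exact permutation p = 0.0179) and the 8 chaperones at -0.11 ± 0.47 (exact p = 0.661), 4 higher and 4 lower. The difference between the arms was 1.66 ± 0.79 (exact p = 0.0179, the smallest that 56 splits allow) and higher in all 3 null than in all 5 control mice. Without Trib3 and Ddit3, known to be high when the arms were drawn, it was 1.24 ± 0.88 (exact p = 0.0179). Without every Atf4 target named by the rule for named genes (Trib3, Ddit3, Atf5, Sesn2 and Vldlr) it was 0.82 ± 0.86 (lowest null 0.18, highest control 0.11, exact p = 0.0179). Of the 10 remaining targets 9 were higher, but their mean overlapped between null and control mice (lowest null 0.18, highest control 0.20, exact p = 0.0357). A rise of the Atf4 arm alone cannot be told apart from a choice of genes already known to be high, because the remaining targets overlapped. The rule used also asked for a remaining difference above its SD over 3 mice, which it was not. That SD is a spread between mice and not the error of the mean difference.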
